A study of Mus musculus with 6 samples.

How the data were processed

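The series holds 6 samples from mouse rib cartilage. A ChIP-seq library for Jun, a subunit of the AP-1 transcription factor, and a matching library of input DNA were prepared from chondrocytes of newborn wild-type ICR mice at postnatal day 1. Per the labels' protocols, 20000000 cells were cross-linked for 10 minutes in 1% formaldehyde, chromatin was sheared by sonication to between 100 and 600 bp, 9 μg of a Jun antibody was used for the precipitation, and libraries were amplified with 18 PCR cycles. The other 4 samples are RNA-seq libraries of sorted rib chondrocytes from Swiss Webster mice carrying a Col10a1mCherry reporter, 2 taken at postnatal day 1, 1 at postnatal day 3 and 1 at embryonic day 18.5. The RNA-seq libraries, for which the submitters' processing notes name TopHat2 and Partek, were not analysed here.

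The measurement used was the list of Jun peaks that the authors deposited. It gives the chromosome, start and end of each peak on the mouse genome build mm9, per the submitters' processing notes, and no header, score, height, p-value, strand or name. The aligner, the peak caller and how the input library entered the calling are not given in the sources used here. The name of the deposited list carries an FDR mark and a further mark, but no label or header explains either, so no threshold is stated here. The list does not name its sample, and it was assigned to the Jun library because no other Jun ChIP sample is among the 6. The number of reads behind the list is likewise unknown, so no peak has a depth or an interval of its own. No ChIP replicate is described, so nothing below has a replicate check, and each test describes how the peaks of this list lie on the genome, not how Jun binding varies between animals. The values of the input library were not used here, so no background level stands beside the peak counts.

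The list was read with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15. Positions are printed counted from 1, as in a genome browser. The position of a peak is the middle of its interval. Peak density is the number of peaks per Mb between the first and the last peak of a chromosome, because chromosome lengths of mm9 were not used here. The 95% intervals of densities are exact Poisson intervals (scipy 1.17.1) and cover counting error only. They are too narrow where peaks lie in groups.

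Clustering was measured as the percentage of peaks whose next peak centre on the chromosome lies within 10 kb. It was set against 1000 random placements of the same number of peaks, drawn uniformly over each chromosome's span of peaks. The permutation test is two-sided, and 0.002 is the smallest p-value that 1000 placements can give. A second kind of placement kept the number of peaks in every 1 Mb bin. The procedure was tested on simulated data with the real chromosome spans and 99162 peaks. With 5% or 20% of uniformly placed peaks moved to within 300 to 5000 bp of another peak, the share lay above all of 200 uniform placements, and with uniform peaks it lay within them. Simulated peaks placed uniformly within their 1 Mb bins also lay above all uniform placements, but within those that keep the bins. An excess over uniform placement alone therefore does not separate close grouping from broad differences in density. Peak numbers were also counted in fixed tiles of 100 kb.

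The rule for named items was fixed before the data were examined. So were the tests and the alternatives, except those stated below to have been chosen after seeing the data. With coordinates alone, the rule names the 10 widest peaks and the 3 tiles of 100 kb with the most peaks. The alternatives fixed beforehand merged peaks within 1000 bp of each other, changed the distance to 2, 5 or 50 kb and changed the placement. Several planned analyses could not be made. The share of peaks in promoters, exons and introns, the AP-1, Sox and other motifs in the peaks, and the peaks near lists of hypertrophic, cartilage, AP-1 and other cell type genes all need the sequence or gene positions of mm9, and the gene table at hand belongs to the later build GRCm38. Coordinates were not converted between builds, so peaks are named by position and not by gene. Comparisons by peak strength, such as peak width against score or the stronger part of the list, need a score. The overlap of Jun with Sox9 peaks, which the study's design text describes, was not analysed here.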

Results

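Jun binding was mapped by ChIP-seq in chondrocytes freshly isolated from the rib cartilage of newborn mice. The study asked how AP-1 factors such as Jun, together with Sox9, the transcription factor that drives cartilage formation, act on chondrocytes as they enlarge into hypertrophic cells. The data were a list of Jun peaks, taken to be that of the 1 Jun library in the series, which was prepared beside 1 input library from the same kind of cells at postnatal day 1. The list held 99162 peaks on 21 mm9 chromosomes. No interval occurred more than 1 time. The read depth behind the list is unknown, and there was no replicate against which a peak could be checked.

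The Jun peaks were narrow. Their median width was 114 bp, with the central 50% of peaks between 88 and 151 bp, against sheared fragments of 100 to 600 bp. Of all peaks, 78995 (79.7%) measured at least 50 but under 200 bp and 13909 (14.0%) at least 200 but under 500 bp. A further 6247 peaks (6.3%) were narrower than 50 bp, the narrowest being 4 bp, and 11 peaks reached 500 bp or more. The peaks together covered 13.4 Mb, and 1497 of them (1.51%) overlapped the peak before them. Many were close neighbours: when peaks within 1000 bp of each other were merged, 74020 regions remained. Of these regions 16330 contained 2 or more peaks, together 41.8% of all peaks, and the fullest region joined 26 peaks.

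The widest peak was the 874 bp interval on chromosome 4 from 11642348 to 11643221, in a 100 kb tile with 18 peaks. The second, of 850 bp, lay on chromosome 6 from 90607670 to 90608519, in a tile with 33. The third, of 764 bp, lay on chromosome 7 from 86241559 to 86242322, inside a tile with 72 peaks. A peak of 757 bp on chromosome 15 (97810228 to 97810984) and one of 664 bp on chromosome 10 (76173394 to 76174057) lay in tiles with 50 and 52 peaks. The remaining 5 of the 10 widest peaks measured 538 to 660 bp and lay on chromosomes 4 (from 45543350), 19 (from 5800559), 11 (from 75580790), 2 (from 104333606) and 18 (from 67563052). Their tiles held 7, 52, 13, 2 and 17 peaks in that order. Which genes these peaks lie in was not determined.

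Jun peaks were spread over all autosomes, were few on the X chromosome and were nearly missing from the Y chromosome. Chromosome 11 had the highest density, 57.7 peaks per Mb (95% interval 56.3 to 59.1, 6842 peaks), followed by chromosome 19 with 52.9 per Mb (51.1 to 54.9, 3072 peaks). Chromosome 14 had the lowest density among the 19 autosomes, 33.3 per Mb (32.2 to 34.3, 3851 peaks), next to chromosome 12 with 33.7 per Mb (32.7 to 34.8). The densest and the sparsest autosome thus differed 1.73-fold, and their counting intervals did not overlap. The X chromosome held 1358 peaks, or 8.46 per Mb (8.01 to 8.92). Its density was 0.211 times the autosomal median of 40.1 per Mb, and the sparsest autosome was still 3.93-fold denser. The 95% counting interval of X alone, over that median taken as fixed, ran from 0.200 to 0.222. It leaves out the spread among autosomes. X made up 6.26% of the summed span and held 1.37% of the peaks. The Y chromosome held 4 peaks, located between 452029 and 2792994. The sex of the animals and the part of Y to which reads can be mapped were not considered here. The low count is therefore no evidence that Jun is absent from Y. Median peak width differed little between the autosomes and X, from 113 to 115 bp on the autosomes and 115.5 bp on X. The 4 peaks on Y had a median of 130.5 bp. These densities were not tested against chromosome length, and the intervals cover counting error only.

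**Figure D1:**
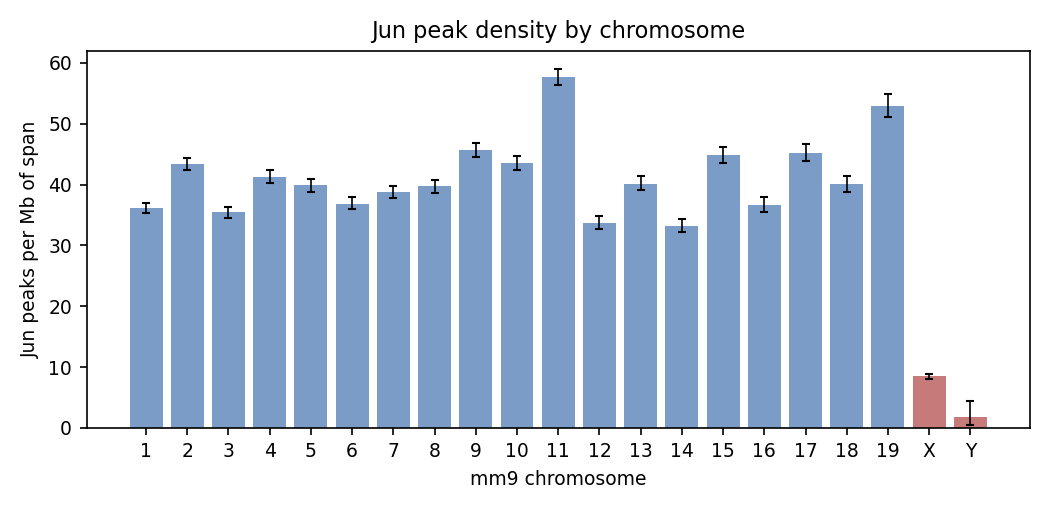
Bars give Jun peaks per Mb between the first and last peak of each mm9 chromosome, and error bars are exact 95% Poisson intervals (counting error only, 1 library). Chromosome 11 stands highest at 57.7 per Mb, and the X chromosome at 8.46 per Mb lies below all 19 autosomes.

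Neighbouring Jun peaks lay close together. The median distance from a peak centre to the next was 5652 bp, with the central 50% of distances between 1117 and 19354 bp. For 61.3% of the peaks the next centre was within 10 kb, against a mean of 33.5% and a highest value of 33.8% in 1000 uniform placements. The observed share was 1.83 times the uniform mean (two-sided permutation test, p = 0.002, the smallest that 1000 placements can give). As a ratio to uniform placement, though not as a difference in percentage points, the excess was larger at short range. Within 2 kb the share was 33.4% against 7.88% under uniform placement, a ratio of 4.24, and within 5 kb it was 47.7% against 18.51%, a ratio of 2.58. At 50 kb the shares were 90.4% and 86.2% (p = 0.002 at each distance by the same permutation test). Distances of 300 to 500 bp separated 7540 neighbouring pairs, and 962 pairs lay closer than 200 bp.

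**Figure D2:**
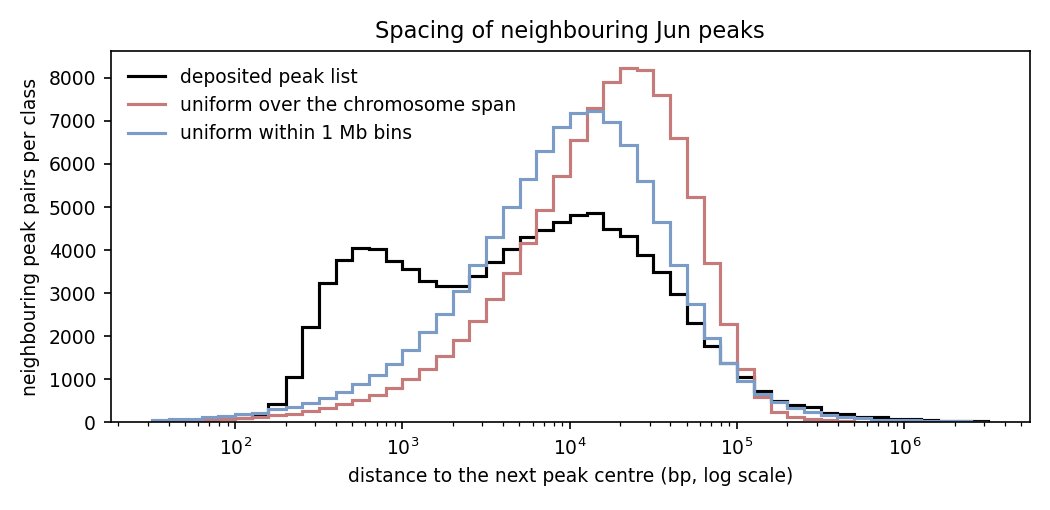
The horizontal axis gives the distance in bp from each peak centre to the next on a log scale, and the vertical axis the number of neighbouring pairs per distance class, for the deposited list and for the mean of 20 placements of each kind. Within 2 kb, 33.4% of the peaks had their next neighbour. The list lies above both kinds of placement in the classes from 158 to 2512 bp. In every shorter class it lies below the placements that keep the 1 Mb bins. At longer distances it lies below both kinds from 6310 to 79433 bp and above both again from 125893 to 1995262 bp.

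When the placement kept the number of peaks in every 1 Mb bin, the mean share within 10 kb rose to 48.4%, and the highest of 1000 placements was 48.8%, so that the observed 61.3% was 1.27 times that mean (permutation test, p = 0.002). At 50 kb this excess was gone, with 90.4% observed against 90.5% (permutation test, p = 0.0579). Against uniform placement, the excess was seen on all 19 autosomes and on X. Each of these 20 chromosomes lay above the highest of 1000 uniform placements of its own peaks. Single chromosomes were not set against placements that keep the 1 Mb bins. Their excess therefore does not separate close grouping from broad differences in density along the chromosome. The autosomal shares within 10 kb ran from 56.9% on chromosome 13 to 66.0% on chromosome 11. On X the share was 42.6%, against 8.1% under uniform placement. The 4 peaks on Y were too few to show clustering.

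Jun peaks were found in most tiles of 100 kb, with a dense minority of tiles, though the peaks themselves covered only 13.4 Mb. A further 9476 tiles held no peak, and the number of occupied tiles was not set against placements. Of the 25644 tiles of 100 kb between the first and last peaks, 16168 (63.0%) held at least 1 peak, with a median of 4. The 545 tiles with 20 or more peaks were 2.13% of the tiles and held 14.9% of the peaks. No uniform placement gave more than 1 such tile, and the placements that kept the 1 Mb bins gave 106 on average and at most 131. The densest tile, on chromosome 4 from 62900001 to 63000000, held 90 peaks. Tiles on chromosome 1 from 92600001 to 92700000 and on chromosome 7 from 124600001 to 124700000 held 80 peaks each. The fullest tile in 1000 placements held 21 peaks under uniform placement and 45 with the 1 Mb bins kept. In these 3 tiles the median distance between neighbouring peaks was 931, 784 and 680 bp, and the peaks covered 18037, 12730 and 13878 bp of sequence. The median peak width there was 149, 128.5 and 137 bp. Over all 14728 peaks in tiles with 20 or more peaks it was 118 bp, against 112 bp for the 3038 peaks that were alone in their tile. The shares of peaks of 200 bp or more differed further, 19.7% in the tiles with 20 or more peaks and 8.49% among the lone peaks. Which place was the fullest changed under some settings chosen after seeing the data. It was the same tile on chromosome 4 with peaks within 1000 bp merged, with 34 regions, but chromosome 1 with 112 peaks for a window of 100 kb at any start, and chromosomes 19 and 15 with 41 and 54 peaks in the first and last 50% of the list.

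**Figure D3:**
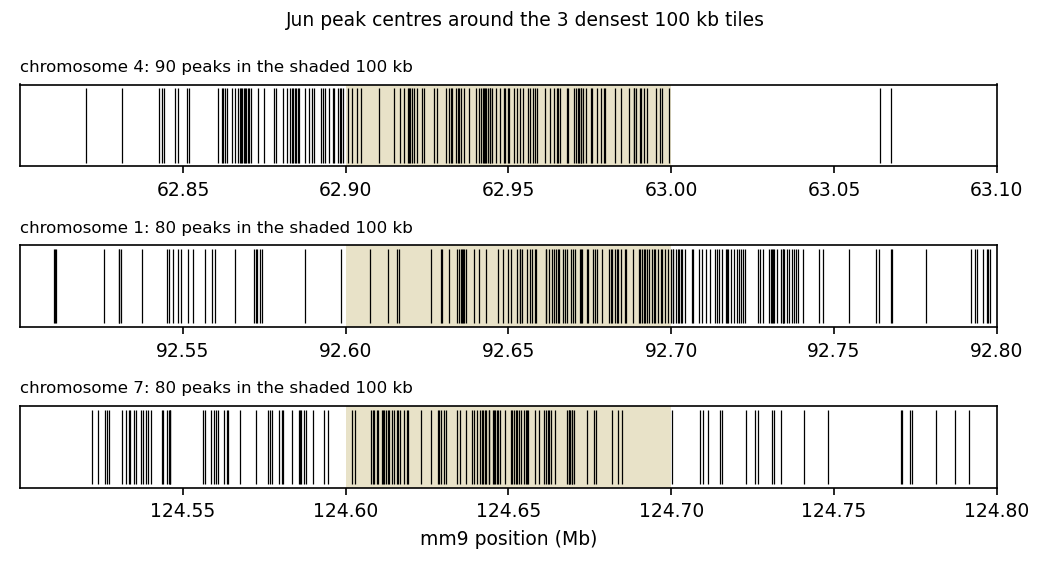
Vertical lines mark Jun peak centres along mm9 positions in Mb, in a window of 300 kb around each of the 3 densest 100 kb tiles, which are shaded. The shaded tiles hold 90, 80 and 80 peaks, and peaks continue beyond the tile borders in each panel.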

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

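Clustering kept its direction and its side of the threshold under 11 of 12 alternatives (permutation p = 0.002 each), with the ratio of observed to placed shares between 1.05, for a next peak within 50 kb, and 4.24, for one within 2 kb. The exception was a next peak within 50 kb with the 1 Mb bins kept, where the ratio was 0.999 (permutation p = 0.0579). The placements there already gave a mean of 90.5%, which leaves the ratio little room to rise. The cause was not tested further. The ratio was 1.82 with peaks within 1000 bp merged, 1.27 with the 1 Mb bins kept and 1.25 with both. Settings that change 2 choices together were chosen after seeing the data. The number of peaks was 74020 after merging and 92915 with peaks of at least 50 bp. Further alternatives chosen after seeing the data took the first or last 50% of the list in its deposited order, whose meaning is not stated, peaks of at least 50 bp, and, for the densest tile, merged peaks and another window. The density of X relative to the autosomal median was 0.162 in the first and 0.253 in the last 50% of the list. The median width was 126 bp after merging, 109 and 121 bp in the first and last 50% of the list, and 117 bp with peaks of at least 50 bp. The densest 100 kb tile held 85 peaks with peaks of at least 50 bp and 34 merged regions, both on the same tile of chromosome 4. It held 41 peaks in the first 50% of the list (chromosome 19, 5800001 to 5900000) and 54 in the last 50% (chromosome 15, 27400001 to 27500000). A window of 100 kb free to start anywhere held 112 peaks on chromosome 1 (92634910 to 92734909). Fewer peaks enter by construction in the merged set and in each part of the list; the cause of the change of place was not tested. Alternatives that need a score, a summit, sequence or mm9 genes, and those by mm9 chromosome length, were not run. Without read depth, a site missing from the list cannot be taken as unbound.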

Other observations

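Chaining peaks whose centres lie within 10 kb of each other gave 38356 groups. These groups, the tests on X, the tests of the order of the list and the test that joins merging with the 1 Mb bins were chosen after seeing the data. Of the groups, 19148 were lone peaks (19.3% of all peaks), 243 held 20 or more peaks (7.8% of all peaks) and 25 held 50 or more. The fullest held 141 peaks over 157 kb on chromosome 4 (62842462 to 62999473). The next held 136 peaks over 169 kb on chromosome 1 (92598601 to 92767891), 128 over 163 kb on chromosome 7 (124521889 to 124684859) and 105 over 228 kb on chromosome 10 (82438439 to 82666162). Further groups of 65 to 86 peaks lay on chromosomes 18 (80800220 to 80916071), 3 (27418203 to 27575680), 7 (86198124 to 86293937), 6 (30983168 to 31082585), 2 (77336134 to 77434524) and 1 (71623958 to 71715992). The longest stretches without a peak were 10.0 Mb on X (from 23400969), 8.64 Mb on X (from 119147398) and 7.72 Mb on chromosome 7 (from 39056482), and unsequenced gaps in mm9 were not separated from them.

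The rows of the list are not in genomic order, and their order is not explained. Widths were more spread later in the list. From the first to the last 10% of the list the 95th percentile of width went from 193 to 396 bp, and the share of peaks under 50 bp from 3.43% to 9.00%. The median went from 106 to 133 bp. The 10 widest peaks did not follow this, with places between 8245 and 47033 of 99162. Place correlated with width at a Spearman's rho of 0.13 and a Pearson's r with log width of 0.090 across peaks, which are not independent replicates (permutation p = 1e-05 for rho, the smallest that 100000 resamples can give). Peaks in tiles with 20 or more peaks made up 19.4% of the first 10% of the list, 12.7% of the third such part and 16.7% of the last. The tile on chromosome 19 from 5800001 to 5900000 had 25 of its 52 peaks in the first 10%, while the densest tile, on chromosome 4, had 4 of 90 there.

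Close spacing of Jun peaks may come from a peak caller that splits broad enrichment, or from broad differences in peak density along the chromosomes. After merging within 1000 bp, 47.6% of the regions still had the next within 10 kb, against at most 26.7% in uniform placements. This argues against splitting at gaps of up to 1000 bp as the whole cause. Enrichment split at wider gaps would survive the merging, so the comparison cannot decide about it. With the number of peaks in every 1 Mb bin kept, the observed 61.3% exceeded the highest placement of 48.8%. With both together, the 47.6% of merged regions exceeded the highest placement of 38.5%. Both kinds of placement drew positions over the whole span or bin, and unsequenced or unmappable sequence was not left out. The excess over them may therefore be overstated, by an amount that was not examined. Grouped binding sites at particular genes, open chromatin and wide enrichment over strongly transcribed genes all stay open, and none was tested without gene positions or the input values.

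The low number of peaks on X is a second pattern. X had 4.85 groups within 10 kb per Mb (95% interval 4.52 to 5.21) and the sparsest autosome 13.6 (12.9 to 14.3). With 8.46 peaks per Mb, X could not have held that many groups at any group size. The peak count alone thus argues against as many groups with fewer peaks each as the whole cause. Whether groups on X were also smaller was not tested. Loss of whole stretches of X would leave the rest as dense as autosomes, but occupied tiles of 100 kb held a mean of 2.83 peaks on X (bootstrap 95% interval 2.58 to 3.08) and at least 5.47 on each autosome. Loss in pieces shorter than a tile could also lower this mean, so the comparison does not cover it, and it was not examined. On X 29.9% of the tiles held a peak, against 55.7% to 77.8% on the autosomes. The mean of the occupied tiles therefore argues against loss of whole stretches only as the whole cause. Such loss as a part of the cause stays open. Lower read coverage of X, as in cells with 1 copy, might remove weaker sites: the X share rose from 0.575% of the first 10% of the list (exact 95% interval 0.436 to 0.744) to 2.36% of the last 10% (2.07 to 2.68), a ratio of 4.11. This explanation remains open because neither the order of the list nor the depth is given, and a lower number of Jun sites near X-linked genes was not tested.

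The fullest group on X held 36 of its 1358 peaks in 38.8 kb (166407867 to 166446661), and these are the last peaks on the chromosome. The next fullest group on X held 15 peaks (20425671 to 20455871). The mouse pseudoautosomal region, shared by X and Y, lies at this end of X, and a candidate explanation is that this end was read at a higher copy number than the rest of X. The 36 peaks had their median place at 33.0% of the list, against 62.4% for the other 1322 peaks on X (two-sided permutation test, p = 0.00042), and 3 of the 36 were in the first 10% of the list, against 4.08% of the others. The explanation stays open, since the 36 peaks are neighbours and not independent, the meaning of the order is not given, and reads from repeated sequence at this end were not examined.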
